A study of Homo sapiens with 6 samples.

How the data were processed

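Gene expression was measured on 6 arrays, 3 from growing WI-38 cells and 3 from WI-38 cells that overexpressed RASv12 and are called senescent in the labels. WI-38 is a normal human diploid fibroblast strain derived from fetal lung. RASv12 is a constitutively active form of the RAS small GTPase, and the labels do not say which RAS gene it came from. Per the labels' protocols, cells were infected by retroviral gene transfer and kept at 3% oxygen. Total RNA was purified on columns, treated with DNase and amplified in 2 rounds before cDNA synthesis, fragmentation and end labelling with kits made for whole-transcript arrays. The sample titles do not say whether control cells received an empty vector. If they did not, infection and RASv12 cannot be told apart. Per the labels, the control samples carried Cy5 and the RASv12 samples Cy3. The probe set identifiers are those of the A array of the Affymetrix Human Genome U133 set, which reads a single colour, so how this pair of dyes was used stays unknown. If the dyes did differ, dye and group cannot be told apart. No label says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

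The authors deposited 1 value table with a linear signal intensity for each probe set, and the submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probes of a probe set into a signal. Its version and scaling target are not given in the sources used here. On each of the 6 arrays the mean intensity after trimming 2% of values from each end lay at 100.0, so the arrays had been scaled to a common brightness before deposit. Deposited intensities ran from 0.0353 to 7370, and median intensity per array was 31.7, 29.8 and 30.0 for control replicates 1 to 3 and 26.1, 29.7 and 33.5 for RASv12 replicates 1 to 3. No 2 arrays held identical values. The number of arrays limits the precision of every value.

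The table held 22283 probe sets. Of these, 68 are control probe sets and were left out, and 22215 were tested. The probe annotation gave 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107. Probe sets with several symbols or none stayed unnamed. Symbols were checked through gene identifiers against RefSeq for assembly GRCh38.p14, where 12 probe sets with 1 symbol found no match and kept the symbol of the annotation. The named probe sets represented 11963 genes. A gene with several probe sets, as 4310 had, was represented by the probe set with the highest mean over all 6 samples, and 40 genes had probe sets called in both directions. Some genes on the study's lists were not analysed here. Genes of the Y chromosome and the X-inactivation transcript entered the counts and are not reported singly.

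Intensities were transformed as log2(value + 16), which compresses the change of dim genes. Array medians on this scale ran from 5.40 to 5.63, further apart than the 0.1 allowed, so quantile normalization between arrays was applied. Differences between groups were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets or over all genes and a threshold of 0.05 on the adjusted p. No dim probe sets were filtered out. Errors of log2 changes are standard errors from this fit, with 3 samples in each group. Signal over background was judged against 27 control probe sets for bacterial transcripts, of which the highest intensity on any array was 27.98. Where all 3 samples of a group, or their mean, lay at or under that intensity, a change is given as "at least" a fold, the brighter group's mean log2 deposited intensity against the dimmer group's, with each dim value raised to that level. No fold is given where both groups lay there. The bound for a group whose mean alone lay there was added after the data were examined, and list medians use the stricter rule of all 3 samples. Log2 changes of such genes depend on the pseudocount and their order is not read.

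Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over 25 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. Counts of members are over all genes tested and, where they differ, also adjusted over the list alone. A list of 12 further sets was written after the data were examined and is adjusted over those 12. The test design, the 25 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 18 set genes, of which 13 were measured, the 10 largest rises and the 10 largest falls by log2 change among genes called with no overlap between the groups, and up to 4 members of each list with the largest moderated t. Members that are named as exceptions to a list's direction, and genes of the further sets, were chosen after their values were seen.

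The procedure was tested on simulated data with 11963 genes and 3 samples per group, with 50 genes changed at each size. It recovered 14% of genes changed by 0.5 on the log2 scale, 72% at 1, 96% at 2 and 100% at 3, and 3.42% of its calls were false. This was 1 run in which far fewer genes changed than the 29.4% called in the data, which makes the adjustment stricter. These shares therefore do not carry over to the real fit. Simulated values were drawn with independent noise after normalization and choice of probe set, so those steps were not tested. Alternatives covered the values as deposited, median centring, pseudocounts of 1 and 64, leaving out the dimmest 25% or 50% of probe sets, the replicate number as a block, trended and robust moderation, array weights, a minimum change of 2-fold, the mean of a gene's probe sets, and leaving out each sample in turn. Scaling each array to its 18 hybridization control probe sets, which read bacterial and phage RNAs added in known amounts to the labelled sample, was added after the data were examined. Figures were drawn with matplotlib 3.10.9.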

Results

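The series compared growing WI-38 fibroblasts with WI-38 fibroblasts made senescent by RASv12, an arrest that normal cells enter when a RAS oncogene is active. Each group had 3 samples, each read on 1 array of 22283 probe sets. Between 48.6% and 54.1% of probe sets per array lay above the brightest of the low bacterial control probe sets. Correlations between arrays over all tested probe sets ran from 0.975 to 0.987 within groups and from 0.912 to 0.928 between groups. The first principal component held 73.8% of the variance and separated the 2 groups. The ratio of 5′ to 3′ signal for GAPDH was 0.999, 1.18 and 1.03 in control replicates 1 to 3 and 1.15, 1.24 and 1.18 in RASv12 replicates 1 to 3. The same ratio for ACTB was 0.71 in control replicate 1, and 0.96 and 0.93 in control replicates 2 and 3 and 0.93, 0.96 and 0.89 in RASv12 replicates 1 to 3. Whether these ratios reflect RNA integrity after amplification with whole-transcript kits was not tested.

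In RASv12 cells, 15 of 20 inflammatory cytokines and chemokines, 12 of 19 RAS and MAPK output genes and 20 of 22 interferon-stimulated genes rose. The cytokine list did not pass with an estimated correlation (adjusted p = 0.072), and its neutrophil chemokine CXCL8 rose by 5.99 ± 0.17 (SE) on the log2 scale. All 43 measured genes of a mitosis list fell, as did 30 of 44 genes of DNA replication, 12 of 18 of recombinational repair, 19 of 28 of collagen and matrix and 11 of 15 of the contractile apparatus. COL3A1, a fibrillar collagen chain, fell by 4.49 on the log2 scale (SE 0.16). Each of these groups is described in turn, with n = 3 samples per group for all values.

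The labels were checked first against HRAS, a RAS family member used in many senescence models. HRAS signal was 215 ± 23.0 (SD, n = 3) in control cells and 853 ± 123 in RASv12 cells, a rise of 1.89 ± 0.15 on the log2 scale with adjusted p = 1.4e-04, and it was higher in 3 of 3 RASv12 samples than in any control sample. A single probe set represented HRAS, and whether it lies inside the introduced sequence was not tested. DUSP6, a phosphatase that ERK signalling induces and that switches ERK off, rose by 3.44 ± 0.15 with adjusted p = 1.2e-05.

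Of 11963 genes, 3519 (29.4%) changed, 1665 up and 1854 down. At least a 2-fold change was seen for 1020 genes, 420 up and 600 down, and at least an 8-fold change for 55 up and 30 down. Over probe sets, 5399 of 22215 were called, 2506 up and 2893 down. The groups did not overlap for 99.9% of the called genes, against 43.0% of all genes and 10% from chance in 3 against 3. Among called genes, 219 lay within the low bacterial controls in both groups. Hybridization control probe sets were lower on the RASv12 arrays by a mean log2 shift of -0.34 (SD 0.12 over 18 probe sets, 18 of 18 lower), with an exact two-sided permutation p = 0.1 over arrays, the smallest that 3 against 3 allow. Scaling the arrays to these controls moved the median of all genes from 0.020 to 0.20 and the split of calls to 2824 up and 1039 down, so that 73.1% of calls were rises against 47.3% in the reported fit. It kept 1663 of the 1665 rises, 1039 of the 1854 falls and 594 of the 600 falls of at least 2-fold.

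The RAS and MAPK output list holds transcripts that ERK signalling induces, many of them feedback inhibitors. Of its 19 measured members, 12 rose, 1 fell and 6 did not pass. Their median was 0.82 (camera adjusted p = 9.0e-07, and adjusted p = 0.032 with an estimated correlation). IER3, an immediate early gene, rose by 3.16 ± 0.098, the ERK phosphatase DUSP5 by 2.46 ± 0.095 and the feedback inhibitor SPRY4 by 1.94 ± 0.090. ETV5, an ETS transcription factor, fell by 0.53, a call that ended with scaling to the hybridization controls. CCND1, the cyclin D1 gene, had a log2 change of -0.018 with adjusted p = 0.93.

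The senescence-associated secretory phenotype is the set of cytokines, proteases and growth factors that senescent cells release. Among 20 measured cytokines and chemokines of this set, 15 rose, 2 fell and 3 did not pass, with a median of 3.87, or 4.81 with dim members at their bound and members dim in both groups left out (camera adjusted p = 8.5e-11). With the correlation between members estimated from the data the list did not pass (adjusted p = 0.072 with an estimated correlation). IL6, which encodes interleukin 6, went from 33.3 to 2458 in intensity, a rise of 5.65 ± 0.090 with adjusted p = 2.7e-07. CXCL8 went from 40.8 to 3504 (adjusted p = 3.2e-06). In control cells, several others were not above the low bacterial controls. IL1B, which encodes interleukin 1 beta, was at least 187-fold higher in RASv12 cells (adjusted p = 4.1e-06), with 2 of its 3 control samples within them. CCL20 was at least 73.0-fold higher in RASv12 cells, CXCL5 at least 63.6-fold, CXCL3 at least 61.3-fold, CXCL2 at least 45.0-fold and the granulocyte growth factor CSF3 at least 28.1-fold, with adjusted p from 2.7e-07 for CXCL3 to 9.9e-06 for CSF3. The 2 members that fell were TNFRSF11B, a decoy receptor of bone turnover, with a log2 change of -1.63, and the lymphocyte cytokine IL15, at least 1.86-fold lower. IL15 lost its call with scaling to the hybridization controls, at a log2 change of -0.79.

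Proteases, their inhibitors and growth factors of the same phenotype moved in both directions. Of 32 measured, 16 rose, 6 fell and 10 did not pass, and 17 rose and 7 fell adjusted over the list alone. Their median was 0.74 (camera adjusted p = 8.8e-06, and adjusted p = 0.042 with an estimated correlation). The stromelysin MMP3 rose by 5.40 ± 0.12, the secreted hormone STC1 by 4.82 ± 0.14, the stress cytokine GDF15 by 4.21 ± 0.12 and the activin subunit INHBA by 3.99 ± 0.13. Among the 6 falls were 4 insulin-like growth factor binding proteins, IGFBP7 (-2.14), IGFBP5 (-1.48), IGFBP6 (-1.35) and IGFBP4 (-1.17). With scaling to the hybridization controls 21 rose and 4 fell, and IGFBP5, at -1.14, was among the falls that lost their call. Among the largest rises outside the lists, PI3, a secreted elastase inhibitor, was at least 66.7-fold higher and PTGS2, the inducible cyclooxygenase, at least 38.7-fold higher.

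Genes of the NF-kB pathway and of the interferon response rose as well. Of 14 NF-kB regulators and targets, 10 rose, 1 fell and 3 did not pass (median 0.91, camera adjusted p = 1.9e-05, and adjusted p = 0.12 with an estimated correlation). The adhesion molecule ICAM1 rose by 3.40 ± 0.10, the NF-kB inhibitor TNFAIP3 by 2.77 ± 0.13 and the transcription factor CEBPB by 0.98 ± 0.090, while CEBPD fell by 0.87, a call that ended with scaling to the hybridization controls. RELB, an NF-kB subunit, was at least 2.26-fold higher. In the interferon list 20 of 22 members rose, none fell and 2 did not pass. On the values as deposited 17 rose, and 19 with median centring. The list median was 1.31, or 1.15 with dim members at their bound (camera adjusted p = 4.8e-13, and adjusted p = 0.032 with an estimated correlation). IFI27 was at least 14.3-fold higher, and the oligoadenylate synthetase-like OASL rose by 3.13 ± 0.098, the antiviral GTPase MX1 by 2.72 ± 0.15 and the ubiquitin-like ISG15 by 2.60 ± 0.14.

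**Figure D1:**
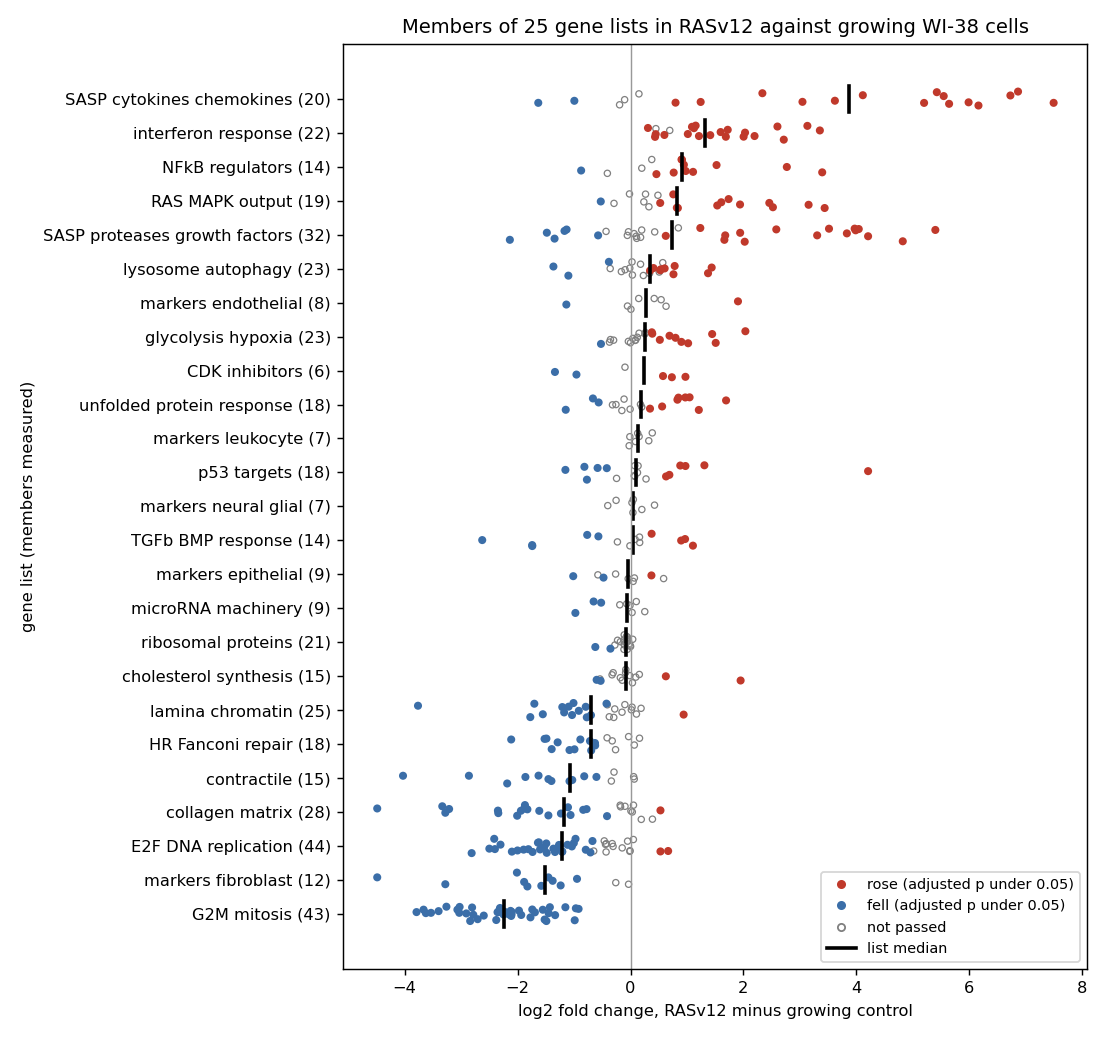
Log2 fold change of RASv12 minus control cells (horizontal axis) for each measured member of 25 gene lists (rows, with the number of measured members), each point a gene and each bar a list median. All 43 mitosis genes lie left of 0, and the median of the secreted cytokines lies at 3.87.

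Proliferation genes fell together. In the G2 and mitosis list 43 of 43 members fell, with a median of -2.23 (camera adjusted p = 4.5e-32, and adjusted p = 0.032 with an estimated correlation). The median was -2.11 with the 23 members that lay within the low controls in RASv12 cells at their bound. The spindle protein PRC1 was at least 17.4-fold lower in RASv12 cells, topoisomerase TOP2A at least 13.4-fold, the kinesin KIF20A at least 9.68-fold, the spindle pole protein ASPM at least 9.25-fold, the chromosomal passenger CDCA8 at least 8.21-fold and cyclin A2 (CCNA2) at least 7.19-fold. MKI67, the Ki-67 proliferation marker, fell by 1.34 on the log2 scale with adjusted p = 1.3e-04, and all 4 of its probe sets fell. The E2F and DNA replication list had 30 of 44 members down, 2 up and 12 not passed, and 33 down and 2 up adjusted over the list alone. Its median was -1.21 (camera adjusted p = 2.2e-14, and adjusted p = 0.036 with an estimated correlation). Thymidylate synthase TYMS fell by 2.81, and the helicase subunit MCM5 (-2.10) and the dUTPase gene DUT (-2.00) fell too, and thymidine kinase TK1 was at least 6.74-fold lower. The 2 members that rose were CCNE1 (0.67), which encodes cyclin E1, and RFC5 (0.53), a clamp loader subunit, and 1 of the 44 members was up on the values as deposited. Homologous recombination and Fanconi genes had 12 of 18 down, none up and 6 not passed, and 13 down adjusted over the list alone. Their median was -0.71 (camera adjusted p = 1.9e-06, and adjusted p = 0.032 with an estimated correlation). H2AX fell by 1.29 on its brightest probe set, while its other probe sets did not pass. FANCI fell by 1.40, and BARD1 was at least 2.45-fold and RAD51AP1 at least 1.83-fold lower.

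Inhibitors of cyclin-dependent kinases moved in both directions. Of 6 measured, 3 rose, 2 fell and 1 did not pass (median 0.24, mean -0.019, camera adjusted p = 0.79). The median was 0 with dim members at their bound and 0.46 with scaling to the hybridization controls. CDKN1A, which encodes p21, rose from 860 ± 71.2 to 1714 ± 93.3 in intensity (SD, n = 3), by 0.97 ± 0.11 on the log2 scale with adjusted p = 7.9e-04. CDKN2A, which encodes p16 and p14ARF, rose by 0.58 ± 0.11 with adjusted p = 0.0067 on its brightest probe set (0.90 with that scaling), while its other 2 probe sets did not pass. CDKN2B was called with adjusted p = 0.0099 at intensities of 1.38 and 12.97, both within the low bacterial controls, so no fold is given. CDKN1B, which encodes p27, fell by 1.34, and CDKN1C, which encodes p57, fell by 0.96. RB1, the retinoblastoma gene, had a log2 change of -0.48 with adjusted p = 0.054 and did not pass. It did pass on the values as deposited (adjusted p = 0.036), with median centring (0.038), without the dimmest 25% (0.042) or 50% (0.024) of probe sets and without RASv12 replicate 2 (0.013). E2F1 had -0.15 with adjusted p = 0.44 on its brighter probe set, and -0.98 with adjusted p = 0.019 on its other, and the mean of both was called at -0.56.

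Targets of p53 had 6 of 18 up, 5 down and 7 not passed, with a median of 0.099 (camera adjusted p = 0.34), or 0.40 with scaling to the hybridization controls. GDF15 and CDKN1A, given above, were among the rises, as were the kinase gene PLK3 (1.31 ± 0.13) and the death receptor TNFRSF10B (0.88 ± 0.10). The 5 falls were DDB2 (-1.15), SESN1 (-0.82), CCNG1 (-0.77), ZMAT3 (-0.58) and FAS (-0.42), and the last 2 were not called with that scaling.

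Of the genes for nuclear lamina and chromatin proteins, chromatin enzymes and histone chaperones included, most of those called were lower. Of 25 measured, 14 fell, 1 rose and 10 did not pass (median -0.70, camera adjusted p = 1.5e-06, and adjusted p = 0.072 with an estimated correlation). With scaling to the hybridization controls the median was -0.38, with 11 down and 2 up. HMGB2, a chromatin protein of dividing cells, went from 555 to 26.2 in intensity, at least 19.3-fold lower. LMNB1, which encodes lamin B1 and whose loss is a marker of senescence, was at least 2.58-fold lower (adjusted p = 3.2e-05). HMGB3 fell by 1.55, and LMNA, which encodes lamins A and C, fell by 1.21 on its brightest probe set. Of the 4 LMNA probe sets 3 were called down, and the remaining one was at -0.31 with adjusted p = 0.30. HMGA2, a chromatin architectural protein, was the member that rose, by 0.94.

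Matrix and contractile genes, which are marks of the fibroblast state, fell. Of 28 collagen and matrix genes, 19 fell, 1 rose and 8 did not pass. Their median was -1.17 (camera adjusted p = 7.6e-10, and adjusted p = 0.033 with an estimated correlation). COL3A1 went from 1556 to 54.2 in intensity (adjusted p = 6.0e-06), and the proteoglycan DCN (-3.28), the matrix glycoprotein FBLN1 (-3.21) and COL1A1 (-1.83) fell with it. THBS2, a matricellular protein, was called up at 0.53 with adjusted p = 0.044, and lost that call on the values as deposited. Fibronectin (FN1) at -0.097 and periostin (POSTN) at 0.053 did not pass, and POSTN was called up at 0.41 with scaling to the hybridization controls, under which 18 of the 28 fell and 5 rose, namely BGN, COL6A1, POSTN, THBS2 and TNC. In the contractile list 11 of 15 fell, none rose and 4 did not pass, and 12 fell adjusted over the list alone. Its median was -1.08 (camera adjusted p = 4.3e-08, and adjusted p = 0.032 with an estimated correlation). TAGLN, an actin-binding protein of contractile cells, fell by 4.03, as did the myosin kinase MYLK (-2.86) and calponin CNN1 (-2.19), and LMOD1 was at least 1.90-fold lower. EFEMP1, a fibulin, fell by 4.03 and MEST, an imprinted gene, fell by 3.65, both among the 10 largest falls. Of 12 fibroblast markers, 5 of them also on the matrix list, 10 fell and 2 did not pass. Their median was -1.52 (camera adjusted p = 4.3e-09, and adjusted p = 0.036 with an estimated correlation). S100A4 fell by 2.01, while the intermediate filament gene VIM was at -0.034 with adjusted p = 0.82.

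Transforming growth factor beta and BMP response genes had 4 of 14 up, 5 down and 5 not passed, with a median of 0.035, a mean of -0.28 and a downward camera test (adjusted p = 0.69). With dim members at their bound the median was -0.0053, and with scaling to the hybridization controls it was 0.26. ID3 and ID2, which are BMP-induced inhibitors of differentiation factors, changed by -2.63 and -1.74, and the inhibitory SMAD6 was at least 2.26-fold lower. TGFB1 itself rose by 0.90 ± 0.086 on its brightest probe set, and the mean of its 2 probe sets, 0.29, was not called.

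**Figure D2:**
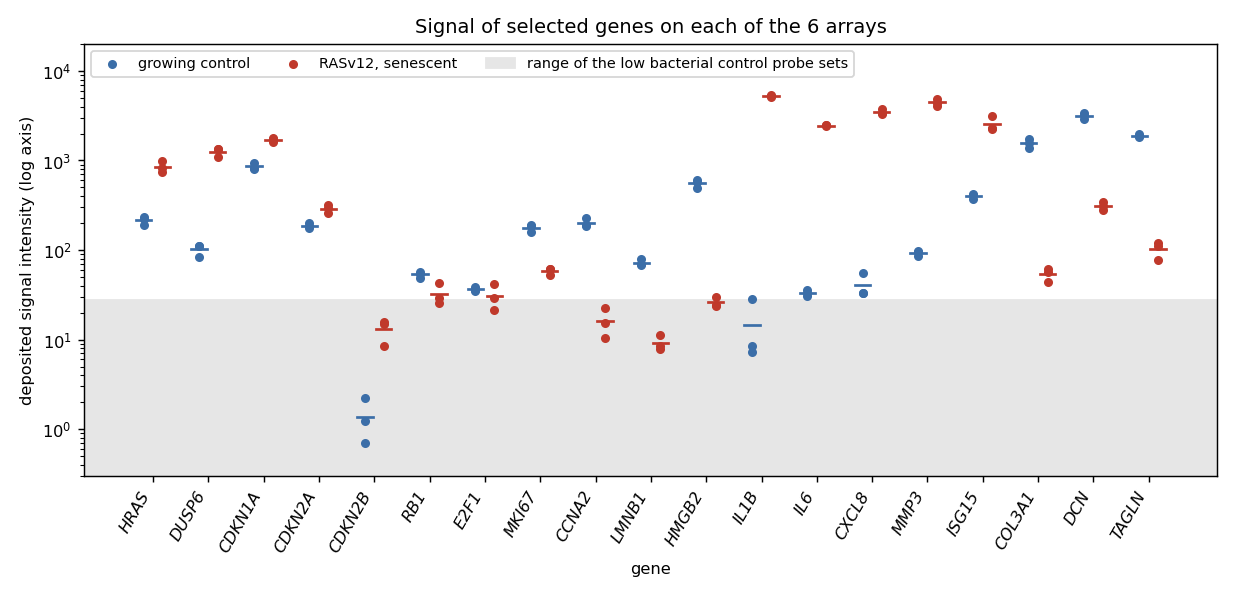
Deposited signal intensity (vertical log axis) of 19 genes on each of the 3 control arrays and 3 RASv12 arrays (points), with group means (bars) and the range of the low bacterial controls shaded. HRAS rises from 215 to 853 and IL6 from 33.3 to 2458, while COL3A1 falls from 1556 to 54.2.

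Organelle and metabolic lists had members in both directions. Of 23 lysosome and autophagy genes, 9 rose, 3 fell and 11 did not pass, and 10 rose and 4 fell adjusted over the list alone (median 0.34). The list passed at camera adjusted p = 0.0498 (adjusted p = 0.44 with an estimated correlation), and leaving out control replicate 1, 2 or 3 or RASv12 replicate 3 each ended that call, with adjusted p = 0.085, 0.060, 0.058 and 0.089. With scaling to the hybridization controls the median was 0.57, with 13 up and 2 down. The protease cathepsin L gene CTSL rose by 1.44 ± 0.16, the autophagy gene ATG7 by 1.37 ± 0.10 and MAP1LC3B by 0.78 ± 0.11, while the lysosomal glucuronidase GUSB fell by 1.10. Glycolysis and hypoxia genes had 10 of 23 up, 1 down and 12 not passed (median 0.26, camera adjusted p = 0.0034, and adjusted p = 0.12 with an estimated correlation), and 16 up and none down at a median of 0.60 with scaling to the hybridization controls. Hexokinase HK2 rose by 2.04 ± 0.17, the mitophagy receptor BNIP3 by 1.51 ± 0.14, neuronal enolase ENO2 by 1.45 ± 0.15 and aldolase ALDOC by 0.90 ± 0.10. The unfolded protein response had 8 of 18 up, 3 down and 7 not passed (median 0.19, or 0.51 with 10 up and 1 down with scaling to the hybridization controls, camera adjusted p = 0.23), with TRIB3 (1.69 ± 0.095), DNAJB9 (1.21 ± 0.12) and SDF2L1 (0.85 ± 0.12) up. SEL1L fell by 0.67 on its brightest probe set, but not on the mean of its probe sets or with that scaling.

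Cholesterol synthesis genes had 2 of 15 up, 2 down and 11 not passed, and 3 down adjusted over the list alone. Their median was -0.087, their mean 0.0031 and their camera test downward (adjusted p = 0.58), and the median was 0.16, with 4 up and none down, with scaling to the hybridization controls. INSIG1, a brake on sterol synthesis, rose by 1.95 ± 0.17 and NSDHL by 0.63 ± 0.11, while SC5D fell by 0.60 and LSS fell by 0.53, both calls that ended with that scaling. LSS also lost its call without control replicate 2 (adjusted p = 0.088) or 3 (0.12) and without RASv12 replicate 1 (0.077) or 2 (0.082).

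In the microRNA machinery list 3 of 9 members fell, none rose and 6 did not pass (median -0.066, camera adjusted p = 0.34), a median that was 0.11, with 3 up and 1 down, with scaling to the hybridization controls. DICER1 fell by 0.98 on its brightest probe set (adjusted p = 0.015), but adjusted p = 0.056 without control replicate 3. Among its other probe sets above the low controls, 1 fell by 1.05 (adjusted p = 0.0045) and 1 did not pass (-0.13, adjusted p = 0.61). DROSHA fell by 0.65 and AGO1 fell by 0.52, calls that both ended with scaling to the hybridization controls, and AGO3, at 0.25 with adjusted p = 0.15, was called up at 0.45 with it (adjusted p = 0.047). Ribosomal protein genes had 2 of 21 down, none up and 19 not passed, and 1 down adjusted over the list alone, with a median of -0.076 that turned to 0.24, with 1 up and none down, with that scaling (camera adjusted p = 0.073). RPL19 fell by 0.62 and RPL3 fell by 0.36, while RPL10A (-0.28) and RPS9 (-0.23) did not pass. RPL10A and RPS9 were called down with a pseudocount of 64, with trended and robust moderation and with the mean of probe sets. RPL10A was called down with array weights and without the dimmest 50% of probe sets too. The other probe set of RPS9 was called down at -0.78 (adjusted p = 0.0040). With scaling to the hybridization controls RPL10A and RPS9 turned to 0.10 and 0.14, and RPL19 and RPL3 were not called. RPL3 also lost its call without control replicate 1 (adjusted p = 0.068) or 3 (0.11) and without RASv12 replicate 2 (0.087) or 3 (0.069).

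None of the lists of markers of other cell types passed camera. Epithelial markers had 1 of 9 up, 2 down and 6 not passed, with a median of -0.041 that was 0.0077, with 2 up and 1 down, with scaling to the hybridization controls (camera adjusted p = 0.58). The keratin gene KRT19 was at least 1.88-fold lower, and KRT8, at least 1.08-fold lower, and KRT18, up by 0.37, lay at the threshold with adjusted p = 0.045 and 0.0499. KRT18 lost its call on leaving out any 1 of the 6 samples (adjusted p from 0.062 to 0.13), and KRT8 with that scaling (adjusted p = 0.077) and on leaving out any control or RASv12 replicate 2 or 3 (adjusted p from 0.096 to 0.13). KRT5 lay within the low controls in both groups, so no fold is given, and did not pass (adjusted p = 0.15), though it did without RASv12 replicate 3 (adjusted p = 0.0045). Endothelial markers had 1 of 8 up, 1 down and 6 not passed (median 0.28, or 0.44 with scaling to the hybridization controls, camera adjusted p = 0.34). TIE1, an endothelial receptor kinase, was at least 1.70-fold higher at an intensity of 48.2 in RASv12 cells, and its relative TEK was at least 2.58-fold lower. Leukocyte markers had 0 of 7 called by limma, and 0 at an unadjusted p under 0.05 (median 0.13, or -0.0059 with dim members at their bound and 0.22 with scaling to the hybridization controls, camera adjusted p = 0.51), and PTPRC, the common leukocyte antigen, stood at 1.98 and 7.02 in intensity, within the low controls. Neural and glial markers had 0 of 7 called by limma, and 1 at an unadjusted p under 0.05 (median 0.043, or 0.11 with that scaling, camera adjusted p = 0.98), and TUBB3, which fibroblasts also express, stood at 2396 and 2791. TUBB3 was called up at 0.56 with that scaling (adjusted p = 0.0088). SNAP25, a synaptic protein gene, had -0.40 with adjusted p = 0.11 on its brighter probe set, while its other probe set was called down (adjusted p = 0.0021), as was the mean of both at -0.79 (adjusted p = 0.0035).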

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

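Scaling to the hybridization controls was chosen after the data were examined, and the other alternatives before. Of 95 named genes that were called, 74 kept their direction and call in every alternative, the minimum change of 2-fold included, and HRAS was one of them. The number of genes called ran from 2587, without control replicate 3, to 3863, with scaling to the hybridization controls, and a minimum change of 2-fold left 1020 genes and 1635 probe sets, since it removes smaller changes by construction. Leaving out 1 sample gave 2587 to 3375 genes and 3706 to 4970 probe sets. Pseudocounts of 1 and 64 gave 2851 and 3630 genes. With the replicate number as a block, 2721 genes were called, 1222 up and 1499 down. The numbers gave no sign of pairing between the groups, since same-numbered samples had deviations correlated at -0.23, -0.028 and -0.070, and 0 of 6 samples correlated best with its own number. With 3 samples per group, a small effect shared by paired samples cannot be excluded. For each change named from here on, the cause was not tested. With an estimated correlation, 5 lists no longer passed at unchanged medians, namely secreted cytokines (3.87), lamina and chromatin (-0.70), NF-kB (0.91), lysosome (0.34) and glycolysis (0.26). The other 9 that had passed still did, with camera adjusted p from 0.032 to 0.042. Their far smaller p-values therefore depend on the use of a preset correlation. Under fry, which does not compare a list with other genes, 6 more lists passed. Upward were p53 targets (0.099), unfolded protein response (0.19) and endothelial markers (0.28). Downward were microRNA machinery (-0.066), ribosomal proteins (-0.076) and TGF beta and BMP, the last at a median of 0.035 and a mean of -0.28. The lysosome list also lost its call with a pseudocount of 1 (0.37), without the dimmest 25% (0.34) or 50% (0.35) of probe sets, with array weights (0.35), with the mean of probe sets (0.23), and on leaving out 1 sample, where its median ran from 0.23 to 0.38. The ribosomal list passed with a pseudocount of 64 (-0.075) and with trended moderation (-0.076). With scaling to the hybridization controls the direction turned for E2F1 (0.050), RPL10A (0.10), RPS9 (0.14), COL6A3 (0.18), VIM (0.23), FN1 (0.26), CCND1 (0.34) and the medians of cholesterol synthesis (0.16), ribosomal proteins (0.24), microRNA machinery (0.11) and epithelial markers (0.0077), none of which had passed, and for 6 of the further sets, of which respiratory chain subunits (0.22) had passed. With the mean of probe sets MBP turned to 9.1e-05. Without the dimmest 25% or 50% of probe sets the CDK inhibitor list turned to -0.098 and -0.19, and without the dimmer 50% endothelial markers turned to -0.25. The test of the neural and glial list changed direction with median centring (0.073), without the dimmest 25% (-0.10) or 50% (0.050), with the block (0.043) and without control replicate 3, and its median over left-out samples ran from -0.012 to 0.078. On leaving out 1 sample, the medians of epithelial markers (-0.096 to 0.028) and TGF beta and BMP (-0.017 to 0.12) changed sign. Those of microRNA machinery (-0.20 to -0.0047), cholesterol synthesis (-0.22 to -0.099), p53 targets (0.063 to 0.19), unfolded protein response (0.099 to 0.25) and endothelial markers (0.18 to 0.31) did not. E2F1 ran from -0.26 to -0.048 and SNAP25 from -0.50 to -0.24. The leukocyte list gave no value without the dimmer 50% of probe sets, since too few members remained. Signal over background limits what dim genes show, and 219 of the called genes lay within the low bacterial controls in both groups.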

Other observations

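The 12 gene sets in the next 2 paragraphs, the tests of the mitosis list and of falls of at least 2-fold, the test of matrix genes and the test of neighbours by older symbols were chosen after the data were examined. Of 21 measured Wnt pathway genes, 12 fell, 1 rose and 8 did not pass (median -0.47, camera adjusted p = 0.0023, and adjusted p = 0.21 with an estimated correlation), and 8 fell and 3 rose at a median of -0.29 with scaling to the hybridization controls. The receptors FZD7 and FZD2 had log2 changes of -3.25 and -3.13, from 649 to 53.9 and from 526 to 45.0 in intensity, and the antagonist SFRP1 (-2.06) and the secreted DKK3 (-1.65) fell as well. Metallothioneins, which bind zinc and copper, had 6 of 8 up, none down and 2 not passed (median 0.58, or 0.93 with that scaling, camera adjusted p = 0.0023, and adjusted p = 0.21 with an estimated correlation). MT1F rose by 1.25 ± 0.12, and MT1G and MT1H by 1.22 and 1.26. Whether probe sets of such related genes read each other's transcripts was not tested, so these rises may not be separate readings. In the prostaglandin set 3 of 15 rose, 3 fell and 9 did not pass (median 0.20, or 0.34 with that scaling, camera adjusted p = 0.54). PTGS2 and the phospholipase PLA2G4A, which releases its substrate, were higher, at least 38.7-fold and 2.12-fold, while the prostaglandin E2 receptor PTGER2 fell by 3.12. Complement genes had 2 of 16 up, 3 down and 11 not passed (median -0.011, turning to 0.22 with that scaling, camera adjusted p = 0.71), with the central component C3 at least 5.84-fold higher, the protease C1R at least 9.12-fold lower and its partner C1S at a log2 change of -2.32.

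Of the 8 remaining sets, 7 changed their counts with the scaling. Proteasome subunits had 7 of 25 up, 2 down and 16 not passed (median 0.21, camera adjusted p = 0.047, and adjusted p = 0.21 with an estimated correlation), and 19 up at a median of 0.57 with scaling to the hybridization controls. Respiratory chain subunits had 7 of 28 down and 21 not passed (median -0.14, camera adjusted p = 0.047, and adjusted p = 0.21 with an estimated correlation), a median that turned to 0.22, with 7 up and 1 down, with that scaling. Antigen presentation genes had 5 of 14 up, 1 down and 8 not passed, and 6 up adjusted over the list alone (median 0.26, camera adjusted p = 0.059), and 10 up and none down at a median of 0.60 with that scaling. Histone genes had 9 of 32 up, 1 down and 22 not passed (camera adjusted p = 0.070), counts that were the same with that scaling, and 22 of the 32 lay within the low controls in both groups. Genes of the oxidative stress response had 2 of 17 up, 6 down and 9 not passed (median -0.25, turning to 0.10 with 4 up and 2 down with that scaling, camera adjusted p = 0.16), and the cystine transporter SLC7A11 fell by 2.65. Imprinted genes had 2 of 17 up, 6 down and 9 not passed, and 3 up adjusted over the list alone (median -0.051, turning to 0.14 with 5 up and 4 down with that scaling, camera adjusted p = 0.48). Integrins had 3 of 16 up, 3 down and 10 not passed (median -0.11, mean 0.0056, camera adjusted p = 0.54), with ITGB3 at least 6.41-fold higher and a median of 0.075, with 4 up and 2 down, with that scaling. Tubulins and actins had 1 of 11 down and 10 not passed, and none down adjusted over the list alone (median -0.0033, turning to 0.35 with 4 up and none down with that scaling, camera adjusted p = 0.79).

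The hybridization controls, added at fixed amounts after the RNA steps, were lower on all 3 RASv12 arrays, with geometric means of 233, 228 and 212 against 282, 281 and 288 on the control arrays. An array brightness difference that the signal scaling turned into gene calls would lower genes by about the shift of these controls, -0.34 on average and -0.51 for the lowest of 18 probe sets (SD 0.12). Falls of at least 2-fold, a log2 change of -1 or lower, exceed that by definition, and 600 genes had such a fall. Only sizes are compared here, and they argue against this explanation as the whole cause of these falls. When arrays were scaled to the controls, all 43 falls of the mitosis list kept their call, and its median went from -2.23 to -2.00 (SD 0.77 over members). The members of the list were fixed before the data were examined, but the test was not. The list's smallest fall, -0.92, already exceeded the shift, so this outcome was likely from the start. The size of these falls argues against the explanation for this list too. For smaller falls it stays open, since a shift of this size ends many such calls whatever their cause, so that the 56.0% of all falls and 35.5% of those under 2-fold that kept theirs do not decide it, and a difference between the groups in RNA content or in the material loaded was not tested.

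Fibroblast matrix transcripts fell widely, and a lower share of fibroblasts in the RASv12 cultures would lower them alike if the other cells made none of them. The tables argue against this form of the explanation, by a rule set after the values were seen. Other cells that make some of these transcripts could lower them unevenly, and this was not tested. For 7 members of the matrix list above the low controls in both groups, BGN, COL6A1, COL6A3, FN1, POSTN, THBS2 and TNC, the 95% interval of the log2 change excluded a fall of 1.5-fold or more, while COL3A1 fell by 4.49. A selective change within the matrix programme of RASv12 cells may be the source, as a hypothesis found and examined on the same data.

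Genes that rose by at least 2-fold lay next to each other in chromosome order more often than chance. Among 11932 genes, 420 of them rises, 45 neighbouring pairs both rose, against a mean of 15.3 in 10000 permutations within expression bins (one-sided permutation p = 0.0001, the smallest they can give, adjusted p = 0.0006 over 6 tests). Gene families with members side by side, such as the CXCL chemokines, might account for this, but without neighbours that share the first 3 letters of their symbols 27 pairs remained against 14.8 (permutation p = 0.0018), and with older symbols also compared 24 pairs against 14.3 (permutation p = 0.0095, adjusted p = 0.014), among them PTGS2 with PLA2G4A and SLC20A1 with IL1A. Such families therefore do not account for all of it, and shared regulation of neighbouring genes is a candidate explanation that was not tested. Falls showed 45 pairs against 31.1 (permutation p = 0.0070).

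Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave as many genes as the 3519 and as many probe sets as the 5399 observed, and the highest of the other splits gave 0 in both cases. Every other split mixes control and RASv12 arrays, so the group difference adds to its residual spread and lowers its count. The 0 is therefore no measure of what chance gives. With 10 splits the share cannot fall under 0.1, so the splits are too few for a share under 0.05.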
